A study of Flechtneria rotunda with 10 samples.

How the data were processed

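RNA was sequenced from strain SEV3VF49 of the green alga, grown for 6 weeks in flasks holding 150 mL of medium and sampled as drops of 40 µL, per the labels' protocols. The libraries were made with a plant RNA-seq kit in which ribosomal RNA of the nucleus, the organelles and bacteria is removed with oligos, 105 of them custom-made, per the labels' protocols. The submitters' processing notes list CASAVA 1.4, Trimmomatic 0.35, Bowtie2 2.2, RSEM 1.2.28 and DESeq2, with no order. The gene identifiers have the form that the Trinity assembler gives, and the column names in the file headers contain the words plant and bowtie2. The names of both tables describe their genes as differentially expressed. By what test or on which comparison these were chosen, which reads were assembled, and any genome build or annotation are not given in the sources used here.

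The first deposited table holds expected counts per assembled gene, estimates of the kind made by RSEM, which the submitters' processing notes list, with 10.1% to 19.7% of the values per library not whole. Their totals differ between libraries, so the deposited counts were taken as not normalised. The second deposited table holds an expression signal scaled by the authors with TMM, per the name of the deposited table. Its column sums run from 644523 to 1935890 with a geometric mean of 1000000, as TPM values divided by a library factor between 0.517 and 1.55 would have. Whether the unscaled values were TPM was judged from these sums alone. Both tables list the same 17148 genes. Spearman's correlation between the tables across genes ran from 0.857 to 0.971 per library. Columns were matched to samples by replicate number and time in their names, and 0 columns belonged to other samples.

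Expected counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 10467 genes. The 6681 removed genes held 0.155% to 1.17% of the counts of a library. Library scaling was by TMM, with factors from 0.529 to 1.54. A quasi-likelihood model (edgeR 4.0.16, R 4.3.3) was fitted to all 10 libraries with 5 stages and no covariate. With 2 libraries per stage, the stages shared 1 estimate of the spread. Each of 7 comparisons was tested two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Standard errors of log2 fold changes were taken as the size of the log2 fold change over the root of the F statistic. Log2 CPM for correlations and principal components used a prior count of 2. The counts give a floor of 3 counts where a gene had none. The floor is taken over the 2 libraries of a stage, and it and the intervals cover counting error only, since no molecular identifiers are recorded.

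The rule for named genes, set before the data were examined, took the 2 largest rises and 2 largest falls in dry against hydrated. They had an adjusted p below 0.05, at least 5 CPM on average in the higher stage and no overlap between the libraries. Gene lists by function had been prepared, but the identifiers are not paired with names in the files, so no list was tested. For overlaps between comparisons that share libraries, 10 sets of unchanged groups were simulated from the fitted means and dispersions. They gave 0.5 called genes on average in dry against hydrated, so their overlaps had to be small. They therefore do not measure what shared libraries add among changed genes. The overlap given for independent lists does not allow for shared libraries either.

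The test was tested on simulated data for dry against hydrated, with 10467 genes of which 200 were changed. edgeR recovered 8.96% of 67 genes changed 2-fold, 52.2% of 67 changed 4-fold and 75.8% of 66 changed 8-fold. These were 6, 35 and 50 correct calls, beside 9 false ones. Rises and falls were equal in number, and far fewer genes were changed than the 4709 called in the data. The simulation therefore does not check the test under a broad shift in composition. Alternatives set before the data were examined were median-of-ratios size factors, library totals alone, no filter (other than removal of genes at 0 throughout), a stricter filter (5 CPM in 2 libraries), DESeq2 1.42.0, limma 3.58.1 on log2 of the deposited normalised signal with pseudocounts of 1 and 0.1 (and with a minimum mean of 1), a 2-fold minimum, the replicate number as a block, fits of only the compared stages, and leaving out each library. The next 5 choices were added after the data were seen: leaving out both late libraries, thinning all libraries to the smallest total, removing each library's trend with relative gene length, derived from the ratio of the 2 tables, splitting genes by their mean in hydrated and dry alone, and leaving out each library for the named genes in rehydrated against dry. The length fit also took up each library's level relative to the mean of all libraries, so removing it re-centred the libraries as well.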

Results

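Gene expression was measured by RNA sequencing in Flechtneria rotunda, a unicellular green alga from a desert, as drops of culture dried on a cover glass and were wetted again. The 10 libraries covered 5 stages with 2 libraries each. Hydrated drops were taken at the start. Early desiccation was sampled at 2.5 h, after 25% of the volume was lost, and late desiccation at 7.5 h, after a loss of 60%. Dry drops were collected at about 24 h, having stayed in the chamber for 11 h once flat. Rehydrated drops were collected 1 h after water was returned. Library totals ran from 1696655 counts in rehydrated replicate 2 to 5409197 in late desiccation replicate 2, over 17148 assembled genes, of which 10467 had enough counts to be tested. These are totals over the genes of the deposited table and may not be the full depth of each library. These genes carry only assembly identifiers, with no gene names, genome positions or functions, so groups of genes are described by when they changed. The labels do not say whether the 2 libraries of a stage came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical. The name of the deposited table describes its genes as differentially expressed, by a choice that is not given. Shares of the tested genes are therefore not shares of all genes of the alga. If the choice was made on these libraries, part of the calls was fixed by it.

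On the first principal component the libraries fell into a wet and drying set and a dry and rehydrated set. Within a stage, log2 CPM of the tested genes correlated at 0.92 to 0.96 across genes. Against the hydrated stage the mean correlation was 0.88 for early desiccation, 0.79 for late desiccation, 0.67 for dry and 0.68 for rehydrated. Rehydrated libraries correlated with dry ones at 0.89 on average. Late desiccation lay between the sets by this measure. Its mean correlation was 0.86 with early desiccation, 0.77 with rehydrated and 0.75 with dry, beside the 0.79 with hydrated. The first principal component held 57.1% of the variance and parted dry and rehydrated from the other stages. The second held 13.1% and ordered hydrated, early and late desiccation. With expected counts from library totals alone, the rehydrated pair had a chi-square per degree of freedom of 42.7, against 5.67 to 8.53 in the other pairs. No pair agreed within sampling noise. A shift in composition between 2 libraries also enters this value. In log2 CPM the rehydrated pair correlated at 0.916, near the 0.924 of the dry pair. A single assembled gene, TRINITY_DN91380_c13_g1, chosen for mention after its values were seen, took between 20.2% and 29.6% of the counts in 9 libraries. It took 13.5% in rehydrated replicate 2 (95% Wilson interval 13.4% to 13.5%, counting error only). Over all 5 stages, 6478 of the 10467 tested genes (61.9%) changed in at least 1 stage by edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05.

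**Figure D1:**
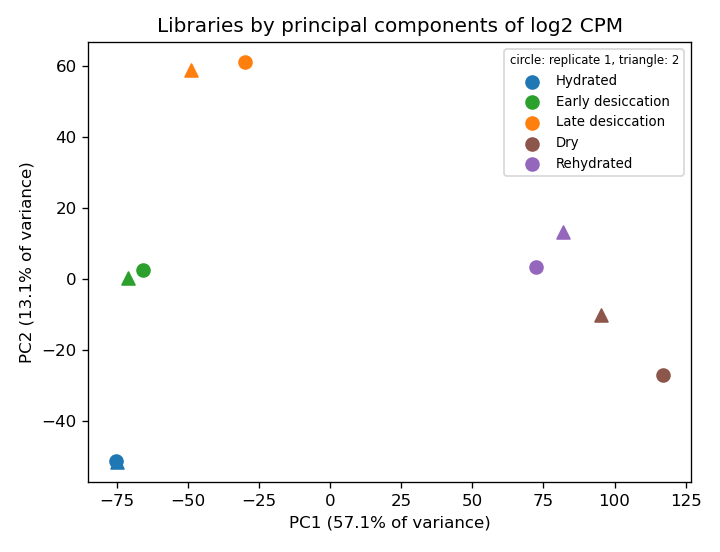
Principal components of log2 CPM of the tested genes, with PC1 (57.1% of the variance) on the x axis and PC2 (13.1%) on the y axis; each point is a library, coloured by stage. Dry and rehydrated libraries lie at PC1 values of 72.3 to 117, and the other 6 libraries lie below 0.

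The first comparison asked which genes differed once 25% of the drop's volume had gone. At early desiccation 529 genes rose and 645 fell against hydrated, 11.2% of those tested. Rising genes had a median log2 fold change of 1.39 (quartiles 1.15 to 1.86), falling genes one of -1.61 (quartiles -2.18 to -1.27), and the median standard error of changed genes was 0.32. Fitted changes of at least 4-fold were found in 112 rising and 208 falling genes. The 529 rising genes held 1.46% ± 0.12 (SD, n = 2) of the counts in hydrated libraries and 4.98% ± 0.39 (SD, n = 2) at early desiccation. The 645 falling genes held 6.65% ± 1.07 and 2.71% ± 0.57 (SD, n = 2 each). Both sets were chosen on these libraries. The early count was 410 without hydrated replicate 1, 417 without hydrated replicate 2, 342 without early replicate 1 and 518 without early replicate 2. With libraries scaled by their totals alone, 793 genes were higher and 232 lower.

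At late desiccation 1206 genes rose and 1402 fell against hydrated, 24.9% of those tested. The median log2 fold change was 1.92 among rising genes (quartiles 1.28 to 2.86) and -1.56 among falling ones (quartiles -2.19 to -1.15), with 577 rising and 438 falling by at least 4-fold. The rising genes went from 2.50% ± 0.22 of the counts in hydrated to 6.07% ± 0.16 at early and 13.0% ± 0.64 at late desiccation (SD, n = 2 each). Between early and late desiccation 640 genes rose and 612 fell, with 307 rises but 88 falls of at least 4-fold. The quartile of lowest mean expression held 120 of these rises and 24 of these falls, and the top quartile 81 and 33. Holding genes with 0 counts in a stage at the floor of 3 counts left 307 and 88. The larger number of genes with reads in the late libraries, described below, may add to this lean, which was not tested. Genes called at early desiccation were also called in the same direction at late desiccation in 333 of 529 rises and 526 of 645 falls. Independent lists of these lengths would share 61.0 and 86.4 genes, and simulated unchanged groups sharing the hydrated libraries gave 0.1 and 0.2 on average. Few genes were called in those groups, so their overlap had to be small. The covariance of the log2 fold changes was 0.96, against 0.15 in the simulations, and their Pearson correlation was 0.60, against 0.56. The 2 hydrated libraries were not split between the comparisons, since each would keep only 1, so part of the excess may come from these shared controls.

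The late libraries differed from the rest in which genes had reads at all. They detected 16728 and 16972 genes, against 10742 to 13774 in the other 8 libraries, and 877 genes had reads in the late libraries only. With limma on the deposited normalised values (pseudocount 1, no filter on low values), 3243 genes were higher and 1058 lower at late desiccation against hydrated, on the log2(value + 1) scale. With genes of a mean below 1 left out of that test, 832 were higher and 856 lower. The late count was 1493 and 1498 without hydrated replicate 1 or 2, and 1359 and 1540 without late replicate 1 or 2. The late against early count of 1252 fell to 571 and 324 without early replicate 1 or 2, and to 297 and 563 without late replicate 1 or 2. Scaled by library totals alone, 1692 genes were higher and 608 lower in late against hydrated, and 417 were higher and 261 lower in late against early.

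**Figure D2:**
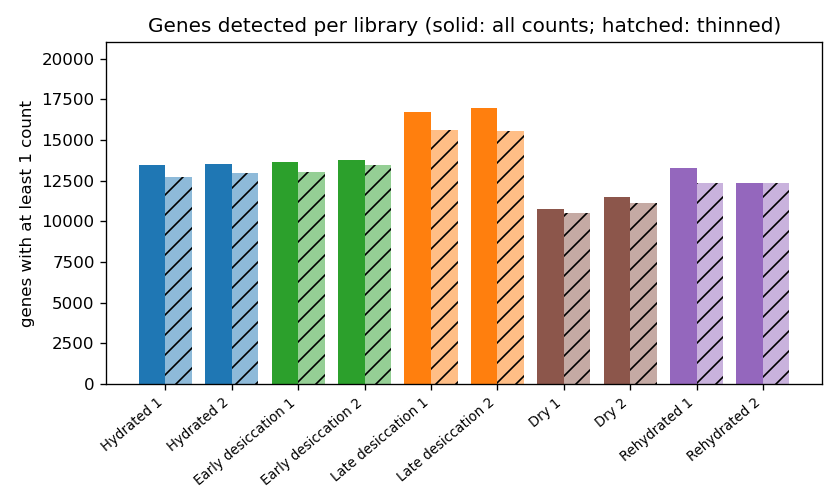
Genes with at least 1 count (y axis, from 0) in each library (x axis), with all counts (solid bars) and after thinning every library to the smallest total (hatched bars). Late desiccation libraries have 16728 and 16972 genes with all counts, and 15630 and 15556 after thinning, above the other 8 libraries.

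**Figure D3:**
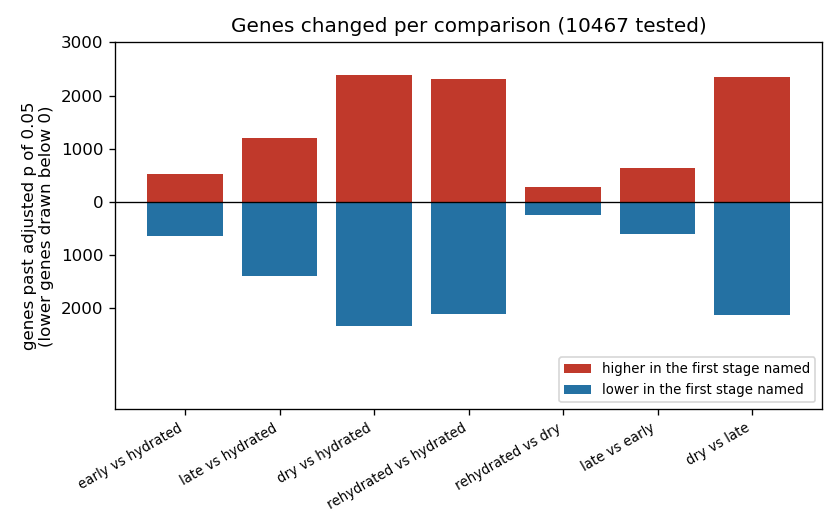
Number of genes past an adjusted p of 0.05 (y axis, edgeR quasi-likelihood test) in each of 7 comparisons (x axis), with genes higher in the first stage named above 0 and lower ones below. Dry against hydrated has 2379 higher and 2330 lower genes, and rehydrated against dry has 286 and 250.

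In dry drops 2379 genes rose and 2330 fell, 45.0% of those tested. The median log2 fold change was 2.12 among rises (quartiles 1.38 to 3.35) and -2.22 among falls (quartiles -3.25 to -1.56), with a median standard error of 0.40 among changed genes. Fitted changes of at least 4-fold were seen in 1269 rising and 1341 falling genes. Of the rising genes 67, and of the falling genes 225, had 0 counts in one of the stages. With such genes held at the bound that 3 counts over a stage set, the medians were 2.11 and -2.07. Changes of at least 4-fold then numbered 1265 and 1237. Rising genes held 17.0% ± 1.35 of the counts in hydrated and 45.6% ± 0.96 in dry libraries, and falling genes went from 11.7% ± 1.34 to 1.67% ± 0.33 (SD, n = 2 each; sets chosen on these libraries). Between late desiccation and dry, 2341 genes rose and 2128 fell. That total of 4469 was 2793 without late replicate 2 and 2945 without dry replicate 1.

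The balance of rises and falls in the dry stage differed with the scaling of the libraries. On the TMM scale the median log2 fold change of all tested genes was -0.28 for dry against hydrated and -0.29 for dry against late, and with library totals alone it was -1.07 and -1.53. In the same order of scales it was 0.00 and 0.42 for early, 0.04 and 0.48 for late and -0.09 and -0.35 for rehydrated against hydrated, and 0.07 and 0.60 for rehydrated against dry. All directions here are relative to the TMM scale, and the amount of RNA per cell was not measured. With library totals alone, 1367 genes were higher and 4176 lower in dry against hydrated, and 814 were higher and 5989 lower in dry against late. With library totals alone, which lower every gene in dry together, 1367 of the 2379 rising genes (57.5%) of dry against hydrated kept their call. With each library's trend with gene length removed, which also re-centres the libraries, 2664 were higher and 1522 lower in dry against late. Without the late libraries, 4348 genes changed between dry and hydrated.

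The 2 genes with the largest fitted rise in dry against hydrated had no reads in hydrated drops. TRINITY_DN73082_c0_g5 had 0 counts in both hydrated libraries and 745 over the 2 dry libraries (307 ± 86.2 CPM, SD, n = 2). It was 555-fold higher, taking 3 counts over the group as the floor (edgeR adjusted p = 0.00205). The lower 95% counting limit of that ratio was 450. It was already at 65.2 ± 18.5 CPM at early desiccation, was split at late desiccation with 303 counts in one library and 0 in the other, and was at 125 ± 4.41 CPM after rehydration (SD, n = 2 each). TRINITY_DN29819_c0_g1 also had 0 counts in the hydrated stage, had 0 and 7 counts in the early and 13 and 8 in the late libraries, and stood at 203 ± 31.2 CPM in dry libraries. It was 372-fold higher than in hydrated at the same floor (edgeR adjusted p = 1.66e-05), with a lower 95% counting limit of 302. After rehydration it was at 60.5 ± 46.4 CPM, a difference from dry that did not pass the threshold (log2 fold change -1.75, SE 0.54, edgeR adjusted p = 0.0822). The log2 fold change was -2.86 without rehydrated replicate 2 and -1.09 without rehydrated replicate 1, each resting on a single rehydrated library.

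The 2 genes with the largest fitted fall had no reads in dry drops. TRINITY_DN67880_c0_g1 fell from 196 ± 54.2 CPM in hydrated to 5.83 ± 4.45 CPM at early desiccation (SD, n = 2 each; log2 fold change -5.06, SE 0.50, edgeR adjusted p = 0.000401). It had 0 counts in both dry libraries, 162-fold lower than in hydrated at the floor of 3 counts (edgeR adjusted p = 7.81e-06). The upper 95% counting limit of the ratio of dry to hydrated was 0.0076. In the rehydrated libraries it had 3 and 1 counts. Rehydrated against hydrated, that was a ratio of 0.0056, with a 95% counting interval of 0.0015 to 0.014. TRINITY_DN72429_c4_g1 kept its level at first, with 178 ± 27.1 CPM in hydrated and 177 ± 10.4 CPM at early desiccation. It then fell to 35.8 ± 9.46 CPM at late desiccation (SD, n = 2 each; log2 fold change against hydrated -2.30, SE 0.50, edgeR adjusted p = 0.00608) and to 0 counts in dry. That was 148-fold lower than in hydrated at the floor (edgeR adjusted p = 2.95e-05), with an upper 95% counting limit of the ratio of 0.0083. In rehydrated drops it had 42 counts in replicate 1 and 4 in replicate 2 (edgeR adjusted p against dry = 0.0468). That call was lost with any library but rehydrated replicate 2 left out, with edgeR adjusted p between 0.0590 and 0.185. All 4 genes share an assembly cluster with other genes of the table, as do 58.0% of tested genes, so reads may be split between similar sequences and their values are uncertain for that reason.

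**Figure D4:**
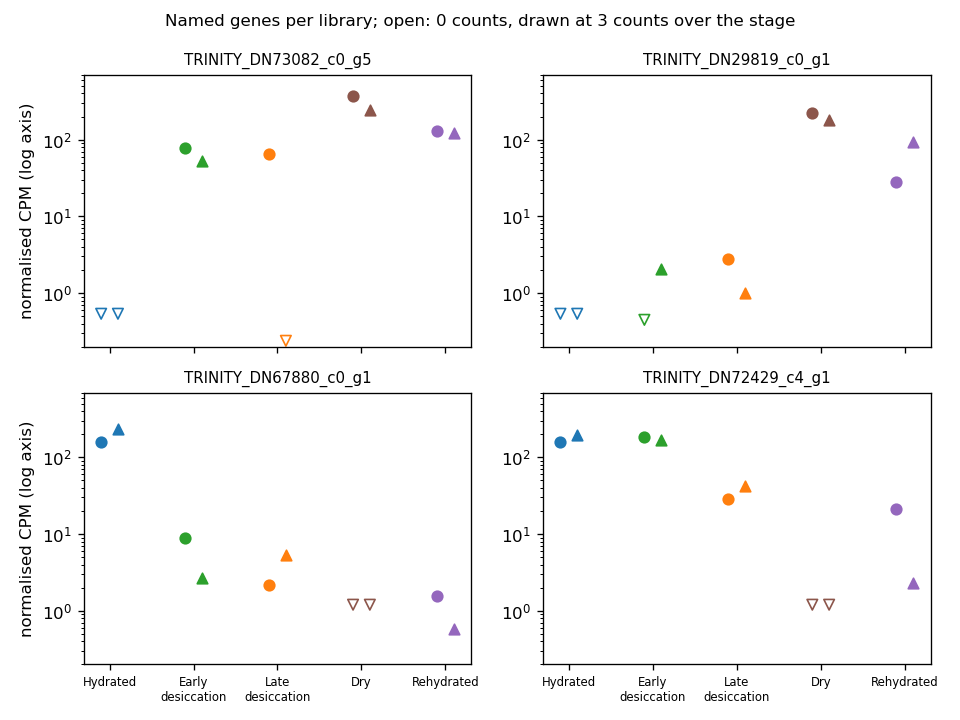
Normalised CPM (y axis, log scale) of the 4 named genes in each library, by stage (x axis); filled circles are replicate 1, filled triangles replicate 2, and open triangles mark 0 counts, drawn at the level of 3 counts over the stage. The 2 upper genes have 0 counts in hydrated and 203 to 307 CPM on average in dry, and the 2 lower genes have 196 and 178 CPM on average in hydrated and 0 counts in dry.

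Most genes called in dry drops were not yet called at the earlier stages. Of the 2379 rising genes, 231 (9.71%) had already risen at early and 695 (29.2%) at late desiccation. Of the 2330 falling genes, 427 (18.3%) had fallen at early and 879 (37.7%) at late desiccation. Independent lists would share 120 rising and 144 falling genes between early and dry, and simulated unchanged groups shared 0.1 and 0.2. The covariance of the early and dry fold changes was 0.83, against 0.15 in the simulations, and their Pearson correlation was 0.31, below the 0.42 of the simulations. Across early, late and dry, 199 genes rose and 391 fell at every stage. Independent lists would share 274 rising and 312 falling genes between late and dry, and simulated unchanged groups shared 0.1 and 0.2. The covariance of the late and dry fold changes was 1.56, against 0.15 in the simulations, their Pearson correlation was 0.47, against 0.45, and the shared hydrated libraries may add to this overlap. Among genes higher at late desiccation than in hydrated, 387 fell from late to dry, and 412 of those lower at late desiccation rose from late to dry. Independent lists would give 245 and 314, and simulated unchanged groups gave 0 of either, with a Pearson correlation of -0.14, against -0.34 in the simulations. Genes rising in dry had median log2 fold changes against hydrated of 0.18 at early desiccation, 0.50 at late desiccation and 2.12 in dry drops, and falling genes had -0.41, -0.72 and -2.22 (2.11 and -2.07 in dry with genes at 0 counts held at their bound).

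**Figure D5:**
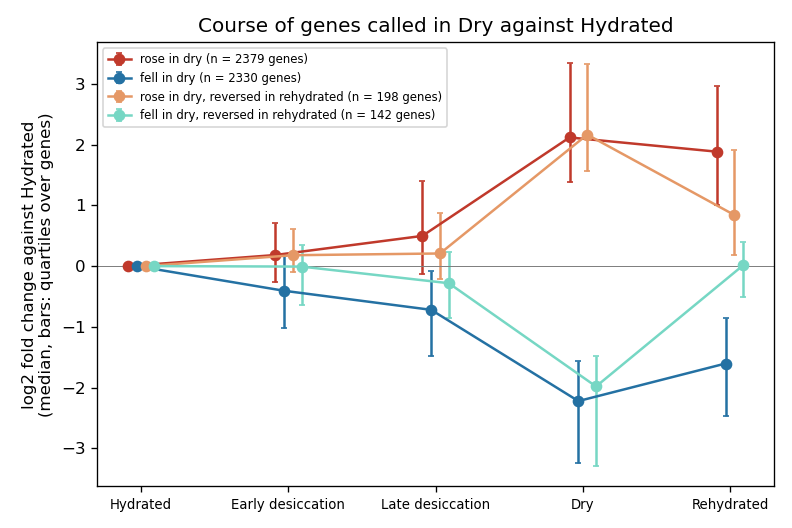
Median log2 fold change against hydrated (y axis; bars are quartiles over genes) at each stage (x axis) for genes called higher or lower in dry, and for those of them that were called in the opposite direction in rehydrated against dry. The 2379 rising genes have a median of 2.12 in dry and 1.88 in rehydrated, and the 142 falling genes called higher in rehydrated than in dry, and chosen on that rise, have a median of 0.01 in rehydrated.

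The rehydration comparisons asked how drops collected 1 h after rehydration differed from dry and from hydrated ones. Against dry, 286 genes rose and 250 fell, 5.12% of those tested, with median log2 fold changes of 1.69 and -1.35. Against hydrated, 2307 genes were higher and 2116 lower in rehydrated drops, 42.3% of those tested. Of the genes that rose in dry, 1821 (76.5%) were still above hydrated in rehydrated drops and 198 (8.32%) had fallen from their dry level. Of the genes that fell in dry, 1510 (64.8%) were still below hydrated and 142 (6.09%) had risen from their dry level. Independent lists would share 524 higher and 471 lower genes between dry and rehydrated against hydrated, simulated unchanged groups shared 0.1 and 0, the covariance was 3.88 against 0.15 in the simulations, and the Pearson correlation was 0.80 against 0.38. Part of this excess may come from the shared hydrated libraries. The genes that rose in dry held 37.2% of the counts in rehydrated replicate 1 and 57.0% in replicate 2. These 142 genes had a median log2 fold change against hydrated of -1.98 in dry and 0.01 in rehydrated (quartiles -0.51 to 0.40). The 198 had medians of 2.16 and 0.84. Because the dry libraries enter both comparisons, chance in them favours reversal. Simulated unchanged groups gave 0 and 0.1 reversed genes, but few genes were called in them, so this had to be small. Independent lists would give 56.8 and 63.7, which does not allow for the shared dry libraries. The covariance was -1.76 against -0.29 in the simulations. The Pearson correlation was -0.52, closer to 0 than the -0.63 of the simulations. Against hydrated, library totals alone gave 1721 higher and 2360 lower genes.

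Some of the genes called between dry and rehydrated had not been called in dry against hydrated. Of the 286 genes that rose from dry to rehydrated, 110 were called in neither direction in dry against hydrated, and 135 stood above the hydrated level after rehydration. The 110 genes had a median log2 fold change against hydrated of -0.27 in dry and 1.38 in rehydrated (quartiles 0.95 to 1.84). Their choice on the rise between these libraries accounts for part of that difference. The 110 genes made up 0.30% ± 0.03 of the counts in hydrated, 0.16% ± 0.04 in dry and 0.63% ± 0.19 in rehydrated libraries (SD, n = 2 each). Of the 250 genes that fell from dry to rehydrated, 45 were not called in dry and 52 stood below the hydrated level.

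The rehydrated against dry count of 536 varied with single libraries and with the scaling. With the edgeR test it was 0 without dry replicate 1 (1906 genes at an unadjusted p below 0.05) and 0 when the 2 stages were fitted alone (1425 genes at an unadjusted p below 0.05), while DESeq2 on all libraries called 802. It was 71 without dry replicate 2, 173 to 223 when any single hydrated, early or late library was left out, and 273 without both late libraries. The scaling moved its balance, with 286 higher and 250 lower genes by TMM, 210 and 290 by median-of-ratios size factors, 140 and 406 with each library's trend with gene length removed, and 770 and 20 by library totals alone. The count of genes changed in dry and reversed, 340 in the full fit, was 184 without both late libraries, 103 to 143 without any single hydrated, early or late library, 58 without dry replicate 2, 224 without rehydrated replicate 1 and 0 without dry replicate 1.

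To compare drying and rewetting without shared libraries, the change from hydrated to late desiccation was set against that from dry to rehydrated. Across the 10467 tested genes, which are not independent replicates, the Pearson correlation was 0.02 and Spearman's rho was 0.01. Over the 16 choices of single libraries the Pearson correlation ran from -0.05 to 0.07. Of the 286 genes higher in rehydrated than in dry, 47 had fallen and 29 had risen at late desiccation. Independent lists would give 38.3 and 33.0. Of the 250 genes lower in rehydrated than in dry, 49 had risen and 39 had fallen at late desiccation, against 28.8 and 33.5 for independent lists. The other comparisons that share no libraries with this one differed in their lean. From hydrated to early desiccation, 29 of the 250 had risen and 7 had fallen, against 12.6 and 15.4 for independent lists. From early to late desiccation, 24 had risen and 40 had fallen, against 15.3 and 14.6. Of the 286 genes, 23 had fallen and 19 had risen from hydrated to early desiccation (17.6 and 14.5 for independent lists), and 12 had fallen and 9 had risen from early to late (16.7 and 17.5). The Pearson correlations were -0.01 for hydrated to early and 0.03 for early to late desiccation.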

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

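The tests in this part were chosen after the result was seen. Outside the tested genes, 871 genes that the low-count filter left out had reads in the late desiccation libraries and in no other stage, 692 of them with at least 3 counts in both late libraries. Their reads are a signal that the comparisons do not use. The hydrated, early, dry and rehydrated stages had 2 genes each with reads in that stage only, against 877 in late desiccation before filtering.

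Greater depth does not account for the excess, since with every library thinned to the smallest total the lower late library still had 15556 genes, against 13441 in the highest other library. A candidate explanation is that the assembled gene set was built or chosen on reads of the late libraries. Only 67 genes with reads elsewhere had none in late, where counting noise alone would give 610. The other stages lacked 2515 to 4696 genes, more than the 162 to 1399 that noise would give. Broader transcription at late desiccation cannot be told apart from this with the 877 genes seen only there, because no gene set chosen without late reads was analysed here.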

How the results depend on the processing

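Total counts for dry against hydrated (3919 to 5543 genes) and rehydrated against hydrated (3590 to 4423) stayed within 1.5 times their main value. So did that for any stage (5216 to 8792). This held under every alternative run for them. The ranges here do not include the fits with a library left out, given below, in which these totals also stayed within 1.5 times. The split of dry against hydrated into rises and falls was less stable than its total. The 4 named genes kept their direction and call in dry against hydrated under every alternative run for them. Scaled by library totals alone, late against early had 678 genes and dry against late 6803. Limma on the deposited signal with a pseudocount of 1 gave 513 for early against hydrated, 4301 for late against hydrated, 3002 for late against early, 8187 for dry against late and 195 reversed genes. With a pseudocount of 0.1 it gave 585 for early against hydrated, 822 for rehydrated against dry, 2589 for late against early and 7729 for dry against late, and with a minimum mean of 1 it gave 570, 1688 and 495 for early against hydrated, late against hydrated and late against early. DESeq2 gave 519 reversed genes. Fits of only the 2 stages compared gave 2063 for early against hydrated, 1905 for late against early and 0 for rehydrated against dry with edgeR (1425 at an unadjusted p below 0.05; DESeq2 on all libraries gave 802). Of the alternatives added after seeing the data, leaving out both late libraries gave 273 for rehydrated against dry and 184 reversed genes. Thinning gave 781 for early against hydrated, 828 for late against early, 158 for rehydrated against dry and 102 reversed genes, which fewer counts would produce by construction. The correlation of drying with rewetting was 0.0917 with no low-count filter. For the other changes the cause was not tested. Leaving out each library in turn gave 342 to 1583 genes for early, 1359 to 3079 for late, 3492 to 5066 for dry and 3255 to 4538 for rehydrated against hydrated, 0 (edgeR; 1906 at an unadjusted p below 0.05) to 495 for rehydrated against dry, 297 to 1644 for late against early, 2793 to 4941 for dry against late, 5359 to 6770 for any stage, 0 to 312 reversed genes and a correlation of -0.005 to 0.05; a stage left with 1 library is assumed to vary like the others. The split of calls also moved with the tool or correction. Rehydrated against dry had 53.4% of its calls upward in the main test, 32.2% with DESeq2 and 25.6% with the length trend removed. In the limma fits with pseudocounts of 1 and 0.1 and with the minimum mean it had 78.9%, 83.2% and 78.8%. Dry against hydrated had 50.5% upward in the main test, 24.7% with library totals alone and 58.1% with the length trend removed. Limma with a pseudocount of 1 gave 2550 higher and 452 lower genes in late against early, and 1918 and 6269 in dry against late. With the minimum mean these were 309 and 186, and 1844 and 3026. The replicate numbers share no stated culture or day, and deviations of same-numbered libraries correlated at 0.00 to 0.14, with 1 of 10 stage pairs, dry with rehydrated, over 0.1. With the replicate block, 730 genes changed between rehydrated and dry and 466 were reversed, against 536 and 340 without it, and no total moved by more than 1.5 times. Its split between rehydrated and dry was 346 higher and 384 lower genes, against 286 and 250, so the lower genes alone moved by more than that and the balance turned.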

Other observations

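Of the tests in this part, the recount without a rehydrated library and the fit with library totals alone were planned; thinning was added after the data were seen but before its own result, and the abundance split, the gene length, time of day and time since transfer tests, and the use of the library totals as a test of the rises were chosen after the results were seen. Rises in dry drops were more frequent among abundant genes. Split into quartiles by mean expression over all libraries, the top quartile held 1296 genes that rose and 446 that fell in dry against hydrated, and the bottom quartile held 195 and 494. With library totals alone the numbers were 742 and 779 in the top quartile and 149 and 960 in the bottom one, so the direction in the top quartile depended on the scaling. The dry libraries enter that mean, so a change shifts a gene's own quartile. Split by the mean log2 CPM of hydrated and dry alone, in which a rise and a fall of one size count alike, the top quartile held 1340 rises and 446 falls and the bottom one 159 and 543. With library totals alone, these were 784 and 748, and 121 and 1043. Some genes had no reads in one of the stages. Among tested genes, 119 with a mean of at least 5 CPM in hydrated had 0 counts in both dry libraries. In the other direction, 58 genes at 5 CPM or more in dry had 0 counts in both hydrated libraries.

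The 4709 genes that changed between dry and hydrated were set against technical causes. Lower totals in the dry libraries as the whole cause are argued against by the 3919 genes still called with all libraries thinned to 1 total. Thinning does not even out the TMM factors, which on all counts were 0.529 and 0.645 in dry and 0.976 and 1.08 in hydrated. Depth per gene may therefore still have been lower in dry, and its part was not tested. A trend with gene length, as RNA breakage could give, is argued against as the whole cause by the 4532 genes called with that trend removed. Fold changes had a Spearman's rho of -0.014 with relative length, so little monotone trend was there to remove. The split still moved, to 2635 higher and 1897 lower genes. Removing the trend also re-centred the libraries, and the median log2 fold change of all tested genes went from -0.28 to -0.06. The moved split can therefore not be credited to gene length. With library totals alone 1367 genes stayed higher, as rises larger than the shift between these 2 scales would. Those 1367 rises were called on either of these 2 scales, which is how they were picked out, so this is no test of scaling as their cause. Scaling as a cause stays open for all rising genes, because the amount of RNA per cell was not measured. A response of the alga to drying remains among the open explanations. Time since transfer to the glass rose together with drying over the early, late and dry stages. Its effect cannot be told apart from that of drying, because drops kept wet for the same times were not analysed here.

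Rehydrated libraries lay nearer to dry than to hydrated ones. Spread between the 2 rehydrated libraries is an unlikely cause, since with either left out the genes changed against hydrated were at least 7.99 times those changed against dry. Time of day is argued against as the whole cause, because dry drops, collected about 24 h after the start, correlated with hydrated libraries at no more than 0.683, below the lowest value for late desiccation of 0.779. These values were known when the test was chosen, and they leave a partial effect of time of day open. A slow return after rehydration and an effect of the time since transfer to the glass cannot be told apart, because 0 libraries of drops kept wet for the same time were analysed here.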
